A study of Mus musculus with 8 samples.

How the data were processed

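RNA of 4 control and 4 dtg heart samples was measured on 1-colour (Cy3) mouse gene expression arrays from 100 ng of labelled total RNA per sample, per the labels' protocols. Groups were taken from the sample titles and genotype labels. The arrays were read with Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes, and the array annotation names mm9, so no coordinates are given here.

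The authors deposited a scanner table per array, in which each spot has a processed signal on a linear intensity scale made with a local background protocol, per the file headers, with its pixel median, local background and quality marks. They also deposited a table of log2 values. Set against the scanner values, that table was quantile normalized log2 processed signal with each probe centred on its median over the 8 arrays (r between 0.9997 and 1 per column). Its column medians were -0.0154, -0.0168, 0.0323 and 0.0178 for controls 1 to 4 and 0.0051, 0.00689, -0.0322 and -0.00946 for dtg 1 to 4. Scale and centring were found from the values, and the tool used for that table is not given in the sources used here. Log2 differences of dim probes depend on how the background was treated.

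The 39429 probes outside the control spots were named through their RefSeq accessions, without versions, in a gene table of assembly GRCm38.p6, used for names alone. A symbol was found for 26369 probes (19987 symbols), and the other 13060 kept the name in the file. Control spots and spots marked as outliers were left out, spots of a probe were averaged on the log2 scale, and the 75th percentile of each array was subtracted. A probe was kept if it was well above background on at least 4 of the 8 arrays, which 26118 were. Of several probes of a gene the one with the highest mean over all arrays was used, leaving 21434 genes and unnamed features, 14829 of them with a symbol. The 75th percentile of signal lay between 737.6 and 1027 intensity units.

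Differences are dtg minus control, tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without covariates) and Benjamini-Hochberg adjustment over all features at a threshold of 0.05. The 31 gene lists were tested with limma's camera at an inter-gene correlation of 0.01 on 21406 features with a value on every array, and adjusted over the 31 lists. An estimated correlation and fry were alternatives. Members were also adjusted over the list alone, and the call this gave was set against the alternatives after it was seen. Single measures per array were compared with two-sided exact permutation tests.

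The genes named were fixed by a rule before the data were examined. It takes Igf1r, then up to 12 genes per direction past the adjusted threshold without overlap between groups, made up to 5 per direction by the smallest unadjusted p where fewer pass, leaving out names that are accessions, clones or gene models. It also takes up to 4 members of each list by smallest unadjusted p, for which 4 were taken from the growth factor signalling list and the called lists and 2 from the others, a choice made after the calls were seen. Some genes that the rule takes are not reported here. Sln, named beside the atrial list, and Arntl, Nppa, Kcnj3 and Kcna5 fall outside the rule and were chosen after their values were seen.

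The lists covered growth factor and insulin signalling, fetal and hypertrophy genes, sarcomere, calcium handling, ion channels, oxidative phosphorylation, mitochondrial biogenesis, fatty acid and glucose metabolism, extracellular matrix, antioxidant genes, paracrine growth factors, cytokines, interferon response, immediate early genes, clock, heat shock, autophagy, p53, cell cycle and ribosomal proteins. Markers of fibroblasts, endothelium, smooth muscle, leukocytes, erythroid cells, adipocytes, atria, skeletal muscle, lung and thymus, and nerve were lists of the same kind.

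Slide was read from the array headers and tried as a block and within each slide. Other alternatives were normexp with an offset of 50, quantile and median scaling, no filter or a filter over all 8 arrays, the mean of all kept probes, the authors' values, the replicate number as a block, an intensity trend, array weights, a test of every kept probe, a threshold of 0.1, and leaving out each sample. The mean signal column was not used here, so normexp was run on the pixel median and the local background median. On control 4 and dtg 4 that fit was pulled by 12 and 4 spots darker than their own local background, with fitted background means of -1740 and -461.9 where the other arrays lay between -19.6 and 11.4. Normexp was therefore also run with such spots left out, which brought all arrays to between 8.49 and 11.4.

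The test was checked on simulated data with known answers, built on the means and residual spread of 21406 genes with 200 changed. With independent noise limma recovered 2.99% of 67 genes changed by 0.5 on the log2 scale, 46.3% of 67 changed by 1 and 83.3% of 66 changed by 2, with 8 false calls. With the measured slide difference of each gene added, 2.76% of unchanged genes reached an unadjusted p under 0.05 without a block and 5.32% with slide as a block. Camera called a simulated shift of 0.3 in the sarcomere list (adjusted p = 8.01e-20), and without the shift it called 0 lists. The noise in that run was independent between genes, so it does not check camera's calls among correlated genes. In the data the estimated correlation was 0.742 for the erythroid and 0.489 for the atrial list.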

Results

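Gene expression was measured in 8 heart samples from male C57BL6 mice, 4 from control animals and 4 from double-transgenic (dtg) animals, each on its own 1-colour array. Control mice carried Cre without a floxed Igf1r gene. The dtg mice carried merCremer, a Cre recombinase that becomes active in the presence of tamoxifen, together with floxed alleles of Igf1r, which encodes the receptor for insulin-like growth factor 1. At an age of 8 months the mice received 4OH-tamoxifen (500 µg, over 10 days in a row), a treatment meant to remove exon 3 of Igf1r, and hearts were collected 6 weeks later. The comparison asks what differs in cardiac gene expression after loss of the receptor, in a study of how diastolic function declines with age. The labels do not say that every sample came from a separate animal, so p-values measure only the spread between these samples, which may be technical.

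Between 59.1% and 71.5% of the 39429 probes lay well above background on each array. The mean share was 64.9% ± 4.8 (SD, n = 4) in control hearts and 67.1% ± 4.41 (SD, n = 4) in dtg hearts, a difference within the spread of the samples (two-sided exact permutation p = 0.514, where the smallest possible p is 0.0286). No spot was saturated on any array. The arrays lay on 2 slides, each with 2 control and 2 dtg hearts. A median of 17.3% of the variance of a gene lay between the slides and 2.88% between the groups. Noise alone also places some variance between any 2 sets of arrays, and it was not subtracted from these shares. Control 1, control 2 and dtg 1, all on slide 1, were the most alike, with Pearson's r across genes of 0.995 for each pair (genes are not independent replicates). Control 3 and dtg 2, on slide 2, formed a similar pair (r = 0.9945). Control 4, dtg 3 and dtg 4 stood apart from the other arrays and from each other, with r between 0.973 and 0.988. The number of arrays limits the precision: the median standard error of a log2 difference was 0.178, so that a gene with that error needed a difference of 0.411 to reach an unadjusted p of 0.05.

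**Figure D1:**
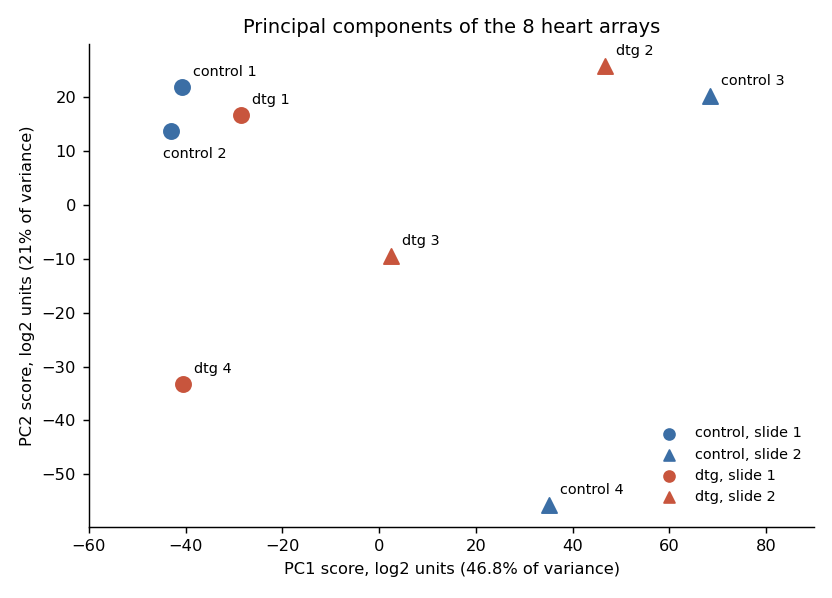
Scores of the 8 arrays on the first (x axis, 46.8% of the variance) and second (y axis, 21% of the variance) principal components of 21406 genes, in log2 units; blue is control, red is dtg, circles are slide 1 and triangles slide 2. The 4 arrays of slide 1 sit between -43.1 and -28.6 on the first component and the 4 of slide 2 between 2.43 and 68.5, while the groups overlap on both components.

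Igf1r signal was lower on average in dtg hearts, but the groups overlapped. The log2 signal relative to the 75th percentile of the array was 0.45 ± 0.40 (SD, n = 4) in control hearts, with values of 0.18, 0.21, 0.38 and 1.04, and 0.02 ± 0.33 (SD, n = 4) in dtg hearts, with values of -0.30, -0.21, 0.17 and 0.40. The difference of -0.43 (SE 0.24), a signal 1.35 times as high in control hearts, did not pass limma's test (adjusted p = 1). It was -0.14 within slide 1 and -0.73 within slide 2, and its SE was 0.24 with slide as a block. Control 4 held the highest value, and without it the difference was -0.24, as it was with the planned normexp background correction. A single probe of the array matched Igf1r, and its position relative to the deleted exon is not known here, so the value does not check the genotype labels.

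No gene passed the adjusted threshold between dtg and control hearts. Among 21434 genes and unnamed features, limma called 0 higher and 0 lower in dtg hearts at an adjusted p under 0.05, and the smallest adjusted p was 1. At an unadjusted p under 0.05 there were 160, of which 132 were higher and 28 lower in dtg hearts, against 1072 that chance would give if genes and arrays were independent. With quantile normalization the corresponding 195 divided into 97 higher and 98 lower. The 4 values of a group lay wholly on one side of the 4 values of the other for 111 genes or features (0.519%), where chance gives 2.86%. The 160 became 280 without control 3, 261 without dtg 1, 331 without dtg 2 and 98 without dtg 3. With slide as a block, 252 reached an unadjusted p under 0.05 and 0 passed the adjusted threshold. Within slide 1 alone these counts were 724 and 0, and within slide 2 alone 495 and 0.

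The genes with the smallest unadjusted p, none of them past the adjusted threshold (adjusted p = 1 for each, limma), included a gene of glycogen storage and a smooth muscle actin. Gys1, the muscle form of glycogen synthase, had a log2 signal of 3.13 ± 0.07 (SD, n = 4) in control and 2.60 ± 0.12 (SD, n = 4) in dtg hearts, 1.44 times as high in controls (log2 difference -0.53, SE 0.10), with all 4 dtg values below all 4 control values and a difference of -0.53 within each slide. Its second probe gave -0.22. The difference was -0.24 with the planned normexp background correction, and -0.50 with spots darker than their local background left out of it. Fabp7, a fatty acid binding protein, differed by -0.50 (SE 0.10) with no overlap between groups, and by -0.50 and -0.51 within slides 1 and 2. Acta2, the smooth muscle alpha actin, differed by -0.37 (SE 0.11), again without overlap, by -0.27 and -0.47 within the slides and by -0.11 with normexp as planned. Pcdhb7 and Svopl completed the 5 lower genes, at -0.33 (SE 0.10) and -0.42 (SE 0.13). Fabp7, Pcdhb7 and Svopl are dim, and a normexp correction without spots darker than their local background, chosen after seeing the data, gave -0.23, -0.17 and -0.18 for them.

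Of the 5 higher genes with the smallest unadjusted p, Apol11b differed by 0.88 (SE 0.13), a 1.84-fold higher mean in dtg hearts, with no overlap between groups and within-slide differences of 0.72 and 1.04. Tlr12, which was well above background on 2 of the 4 control arrays, differed by 0.75 (SE 0.20) and Agbl2 by 0.47 (SE 0.13). Cox7b2 differed by 0.69 (SE 0.20). Gab3 differed by 0.77 (SE 0.23), with dtg 4 the highest at 6.27 (0.55 without it, and 0.68 without control 3), while its second probe gave 0.17. None of these 5 passed the adjusted threshold. All but Gab3 are dim, and the normexp correction without dark spots gave 0.37 for Apol11b, 0.16 for Tlr12, 0.13 for Agbl2 and 0.20 for Cox7b2. With normexp as planned, Apol11b and Tlr12 differed by 0.16 and 0.012, and Agbl2 and Cox7b2 turned direction, to -0.032 and -0.017. With quantile normalization Tlr12 differed by 0.50 and Agbl2 by 0.17. Without control 4, dtg 3 and dtg 4, and with slide as a block, Gab3 differed by 0.50.

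**Figure D2:**
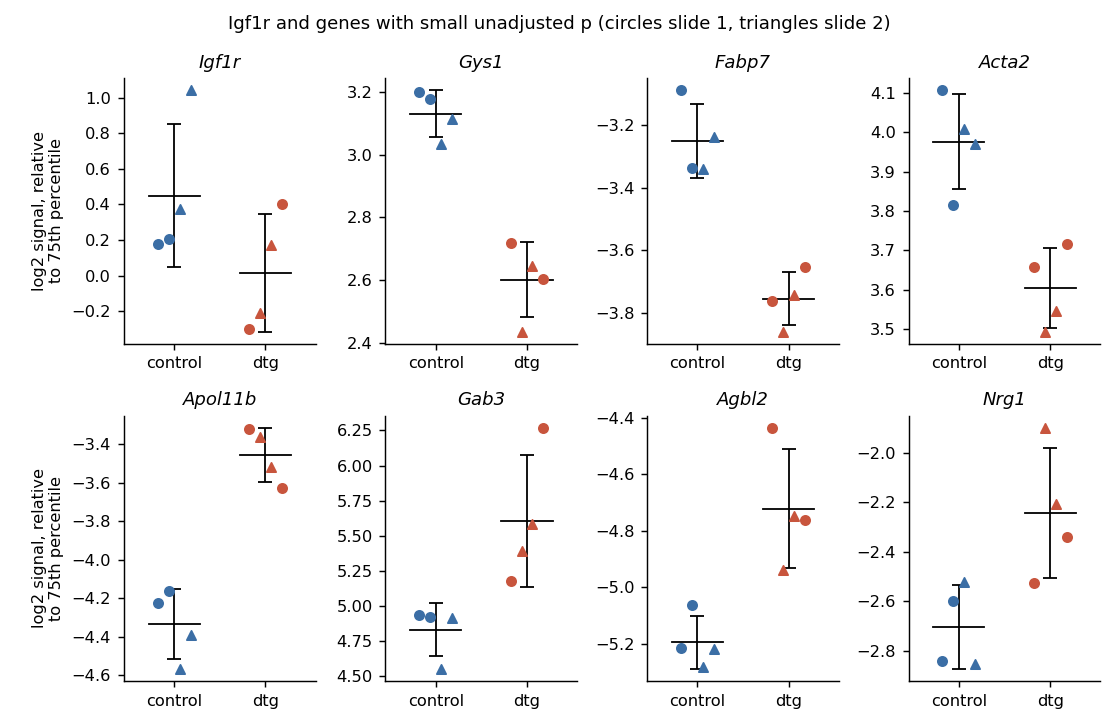
Log2 signal relative to the 75th percentile of each array (y axis, a separate range per panel) for Igf1r and 7 genes with small unadjusted p in 4 control (blue) and 4 dtg (red) hearts; circles are slide 1, triangles slide 2, the wide bar is the mean and the whiskers are ± 1 SD. Igf1r values overlap between groups, whereas Gys1 lies between 2.44 and 2.72 in dtg hearts and between 3.04 and 3.20 in control hearts.

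Of 31 gene lists fixed before the data were examined, limma's camera at its preset correlation called 5, and with an estimated correlation it called none, nor did limma's fry call any. Most or all members of the erythroid and clock lists stood higher in dtg hearts, and most of the atrial, fatty acid and smooth muscle lists stood lower. In none of the 31 lists did a member pass the threshold over all genes, and adjusted over the list alone 1 gene did, Gys1 in the glucose list (adjusted p = 0.0204, limma). The adjustment over a list alone makes no allowance for the 31 lists in which it was run. That call of Gys1 was lost without control 1 (adjusted p = 0.0805), control 2 (adjusted p = 0.0972), dtg 2 (adjusted p = 0.0773), dtg 3 (adjusted p = 0.0577) or dtg 4 (adjusted p = 0.0602), and its adjusted p ranged from 0.00375 to 0.734 over the alternatives. The 0.734 came with normexp as planned, and with dark spots left out of it the adjusted p of Gys1 was 0.0116 (limma). The 5 lists became 8 without control 1, 3 without control 3 or control 4, and 2 without dtg 4.

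Erythroid markers had the smallest p. All 6 measured members were higher in dtg hearts, with a median log2 difference of 0.34 (camera adjusted p = 2.41e-05; adjusted p = 0.39 with an estimated correlation). The globin genes Hbb-b2, Hba-a1 and Hba-a2 differed by 0.50 (SE 0.21), 0.42 (SE 0.21) and 0.25 (SE 0.19), and Alas2, the erythroid enzyme of haem synthesis, by 0.43 (SE 0.21), or 0.60 without dtg 3 and 0.11 within slide 2. None passed limma's test singly. Within slide 2 the 3 globin genes differed by 0.15, 0.088 and -0.0092, without control 1 Hba-a1 differed by 0.26, and Hba-a2 by 0.14 without control 1, 0.41 without control 4 and 0.17 without dtg 4. The median was 0.65 within slide 1 and 0.039 within slide 2, where the list was not called (adjusted p = 0.958), and with slide as a block the call held (adjusted p = 0.000566). Without control 1 the median was 0.20 with the call kept. It was 0.59 with normexp as planned and also without control 4, dtg 3 and dtg 4 with slide as a block. Over the alternatives the adjusted p ranged from 1.88e-13 to 0.958.

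Atrial markers were lower on average in dtg hearts but varied more between hearts of a group than between groups. Of 13 members, 12 were lower, with a median of -0.62 (camera adjusted p = 0.000715; adjusted p = 0.425 with an estimated correlation). Myl7, the atrial myosin light chain, spanned a 19.4-fold range among control and a 14.6-fold range among dtg hearts, and sarcolipin (Sln) a 30.5-fold and an 18-fold range. The mean log2 signal of Myl7, Myl4 and Sln was 4.88 ± 1.94 (SD, n = 4) in control and 3.93 ± 1.76 (SD, n = 4) in dtg hearts (two-sided exact permutation p = 0.514). The direction turned between slides, with a median of 1.36 within slide 1 and -2.61 within slide 2, and array weights gave 0.47 without a call (adjusted p = 0.383). Normexp as planned gave -0.32 with the call kept. With slide as a block the adjusted p was 0.00443, and the call was lost without control 3 (adjusted p = 0.377), control 4 (adjusted p = 0.185) or dtg 2 (adjusted p = 0.0658), with a range from 5.88e-25 to 0.908 over the alternatives. The median was -0.35, -0.29 and -0.32 without these, and -1.14 without control 2, -0.27 without dtg 3 and -1.01 without dtg 4. The call was also lost without control 4, dtg 3 and dtg 4 with slide as a block (median -0.40, adjusted p = 0.242). With the mean of Myl7, Myl4 and Sln as a covariate the median was -0.017 (adjusted p = 0.413). These 3 genes are members of the list, so that covariate takes out the list's own difference and the loss decides nothing.

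Fatty acid genes tended lower: 19 of 26 members were below the control mean and 7 above it, with a median of -0.036 (camera adjusted p = 0.00224; adjusted p = 0.39 with an estimated correlation). The acyl-CoA thioesterases Acot2 and Acot1 differed by -0.41 (SE 0.13) and -0.33 (SE 0.20), whereas lipoprotein lipase (Lpl) differed by 0.16 (SE 0.09), none past the threshold. Acot1 differed by -0.18 without control 4, -0.20 without dtg 2 and 0.018 within slide 1, Acot2 by -0.15 within slide 1, and Lpl by 0.076 with median scaling and 0.44 with normexp as planned. The median was 0.026 within slide 1, -0.18 within slide 2 and 0.23 with normexp as planned, and with slide as a block the adjusted p was 0.00586. The call was lost without control 3 (adjusted p = 0.367), control 4 (adjusted p = 0.256) or dtg 4 (adjusted p = 0.103), with a range from 1.55e-06 to 0.939 over the alternatives. The median was -0.081 without control 1, -0.069 without control 2, -0.0027 without control 4, -0.022 without dtg 2, -0.085 without dtg 3 and -0.074 without dtg 4. The call was also lost without control 4, dtg 3 and dtg 4 with slide as a block (adjusted p = 0.347), with array weights (median -0.0082, adjusted p = 0.939), with the first principal component as a covariate (adjusted p = 0.0582), within slide 1 (adjusted p = 0.752) and with normexp as planned (adjusted p = 0.064). The median was -0.075 with quantile normalization, -0.072 with the deposited values and -0.12 with median scaling. Atrial markers stood lower in the same comparison, with a median of -0.62, and so did adipocyte markers, with a median of -0.12 and no call.

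Smooth muscle and pericyte markers were lower for 8 of 12 members, with a median of -0.080 (camera adjusted p = 0.00798; adjusted p = 0.39 with an estimated correlation). After Acta2, the members with the smallest p were Myh11 at -0.28 (SE 0.17), Mylk at -0.16 (SE 0.16) and Tagln at -0.12 (SE 0.12), none past the threshold. Myh11 differed by -0.14 without dtg 4, Mylk by -0.032 without control 1, -0.25 without control 4 and 0.014 within slide 2, and Tagln by -0.035 without dtg 3, -0.19 without dtg 4, 0.045 within slide 1 and 0.13 with normexp as planned. The median was -0.17 within slide 1, 0.032 within slide 2 and 0.11 with normexp as planned, with an adjusted p of 0.016 with slide as a block. The call was lost with quantile normalization (adjusted p = 0.0914), and without control 1 (adjusted p = 0.0638), control 3 (adjusted p = 0.367) or dtg 4 (adjusted p = 0.325), with a range from 0.00214 to 0.933 over the alternatives. The median was -0.033 without control 1, -0.012 without control 3, -0.13 without dtg 2, -0.044 without dtg 3 and -0.16 with median scaling. The call was also lost without control 4, dtg 3 and dtg 4 with slide as a block (median -0.028, adjusted p = 0.283), with array weights (adjusted p = 0.383), the first principal component as a covariate (adjusted p = 0.0643), the deposited values (adjusted p = 0.0892) or normexp as planned (adjusted p = 0.933). Neither slide alone gave a call (adjusted p = 0.315 within slide 1 and 0.354 within slide 2).

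Clock genes were higher for 13 of 19 members, with a median of 0.29 (camera adjusted p = 0.0389; adjusted p = 0.39 with an estimated correlation). Ciart, a repressor within the clock, differed by 2.18 (SE 0.92), although it was well above background on only 2 of the 4 control arrays, and the clock-controlled factor Dbp by 1.10 (SE 0.58). Bhlhe41 differed by 0.52 (SE 0.21) and Nfil3, which binds the sites that Dbp binds, by -0.53 (SE 0.18). Arntl, which peaks opposite to Dbp, lay between -0.55 and 0.807 in control and between -1.24 and -0.0863 in dtg hearts. The list thus holds genes of opposite phase, so its median is not a level of the clock as a whole. Dbp was lowest in control 1 and control 2, at 2.35 and 3.06, and lay between 4.40 and 5.47 in the other 6 hearts. Within slide 2, Ciart differed by 0.57, Dbp by -0.030 and Nfil3 by -0.12. Without control 1, Ciart differed by 1.43 and Dbp by 0.63, without dtg 3 Bhlhe41 differed by 0.34, and with normexp as planned Ciart and Bhlhe41 differed by 0.33 and 0.043. The list median was 0.47 within slide 1 and -0.0050 within slide 2, and the call was lost with slide as a block (adjusted p = 0.058). It was also lost without control 1 (adjusted p = 0.359), control 2 (adjusted p = 0.194), control 4 (adjusted p = 0.071), dtg 2 (adjusted p = 0.301) or dtg 4 (adjusted p = 0.103), with a range from 0.00446 to 0.928 over the alternatives, and the median was 0.19 without control 1. Further losses came without a filter on dim probes (adjusted p = 0.264), with probes above background on all 8 arrays (adjusted p = 0.0677), with the mean of all kept probes (adjusted p = 0.062), within slide 2 (adjusted p = 0.928) and without control 4, dtg 3 and dtg 4 with slide as a block (adjusted p = 0.12). Normexp as planned kept the call (adjusted p = 0.018) with a median of 0.043.

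**Figure D3:**
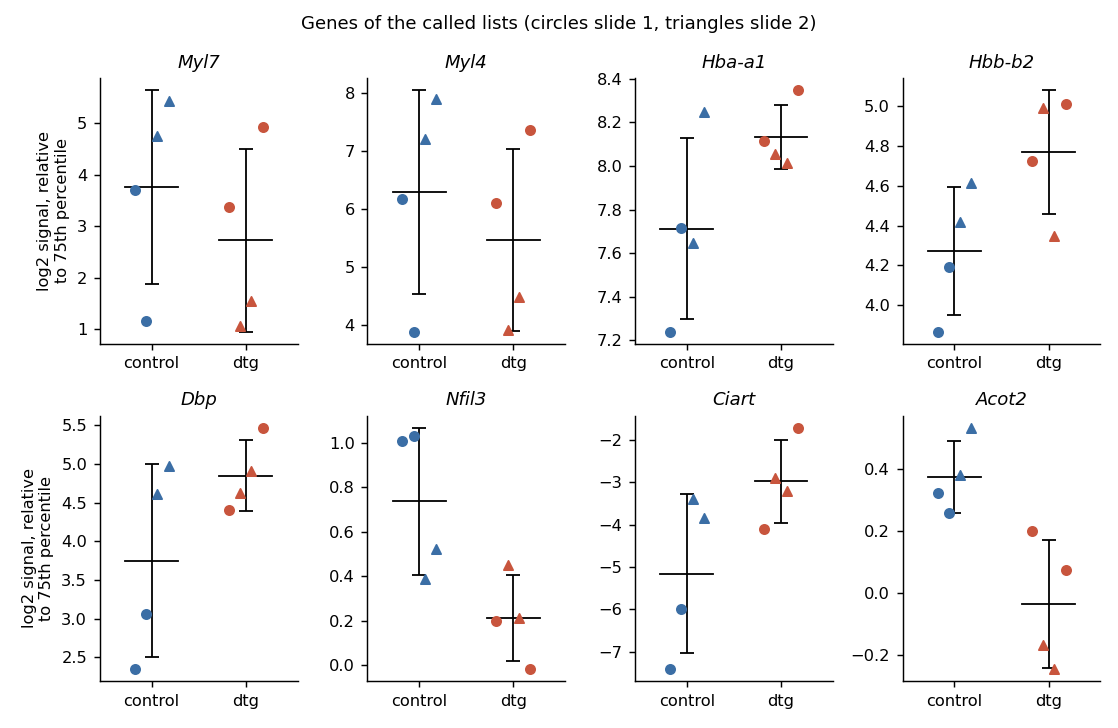
Log2 signal relative to the 75th percentile of each array (y axis, a separate range per panel) for 8 members of the called lists in 4 control (blue) and 4 dtg (red) hearts; circles are slide 1, triangles slide 2, the wide bar is the mean and the whiskers are ± 1 SD. Myl7 and Myl4 are low in control 2, dtg 2 and dtg 3 alike, and Dbp and Ciart are lowest in control 1 and control 2.

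Genes of insulin-like growth factor and insulin signalling were not called with all 8 hearts and the chosen processing (12 of 28 higher, 16 lower, camera adjusted p = 0.151). Camera called the list, as lower, without dtg 2 (adjusted p = 0.0438) and without a filter on dim probes (adjusted p = 0.0419), with a range from 0.0419 to 0.966 over the alternatives. After Igf1r, the members with the smallest p were Igfbp5 at -0.22 (SE 0.13) and the adaptor Irs1 at -0.20 (SE 0.13), with a second probe of Irs1 at 0.036. Igfbp5 differed by -0.13 without dtg 3 and -0.013 with normexp as planned, and Irs1 by -0.12 without control 4 and 0.048 with normexp as planned. Autophagy and atrophy genes that FoxO factors drive were not called either (7 of 20 higher, 13 lower, adjusted p = 0.192), with Sesn3 at -0.22 (SE 0.12) and Sesn1 at 0.16 (SE 0.11). That list was called as lower without control 1 (adjusted p = 0.0326) and without dtg 2 (adjusted p = 0.0438), and as higher with normexp as planned (adjusted p = 0.0162), with a range from 0.0162 to 0.96 over the alternatives. Sesn3 differed by -0.13 without control 1 and -0.065 within slide 2, and Sesn1 by 0.082 with median scaling and 0.42 with normexp as planned.

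Genes of contraction and relaxation gave no call with all 8 hearts and the chosen processing. Sarcomere genes were higher for 10 and lower for 12 of 22 (camera adjusted p = 0.543), with Tcap at 0.36 (SE 0.19) and Myot at 0.25 (SE 0.18). The sarcomere list was called, as higher, with normexp as planned (adjusted p = 9.16e-08, with a range up to 0.997 over the alternatives). With dark spots left out of normexp it was not called. Tcap differed by 0.22 without control 1 and 0.030 within slide 2, and Myot by 0.41 without control 4 and -0.067 within slide 2. Calcium handling genes were higher for 12 and lower for 10 of 22 (adjusted p = 0.709), with the sodium-calcium exchanger Slc8a1 at -0.16 (SE 0.15) and the channel Cacna1c at -0.19 (SE 0.17). Slc8a1 differed by -0.11 without control 1, -0.074 without control 2, -0.25 without control 3 and -0.011 within slide 2, and Cacna1c by -0.31 without dtg 3, -0.055 without dtg 4 and -0.029 within slide 2. Fetal and hypertrophy genes were higher for 7 and lower for 11 of 18 (adjusted p = 0.177), with Acta1 at -0.40 (SE 0.30) and the natriuretic peptide gene Nppb at 0.22 (SE 0.22). The Nppb difference rested largely on dtg 3, without which it was 0.026, and it was 0.11 without control 3 and -0.030 within slide 1. Acta1 differed by -0.60 without control 3, -0.17 without dtg 4 and 0.26 within slide 2. The fetal list was called, as lower, without control 2 (adjusted p = 0.0384, with a range up to 0.956 over the alternatives). The fetal list shares Nppa and Mybphl, the calcium list Sln, and the ion channel list Kcnj3 and Kcna5, with the atrial list. Ion channel genes were higher for 5 and lower for 13 of 18 (adjusted p = 0.179), with Abcc9 at 0.24 (SE 0.11) and Cacna1g at -0.21 (SE 0.11). Cacna1g differed by -0.13 without control 1 and -0.084 within slide 2, and Abcc9 by 0.47 with normexp as planned and 0.12 without control 4, dtg 3 and dtg 4 and with slide as a block. The calcium and ion channel lists were called in none of the 27 alternatives.

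Energy metabolism outside the fatty acid list was not called with all 8 hearts and the chosen processing. Oxidative phosphorylation genes were higher for 13 and lower for 17 of 30 (camera adjusted p = 0.463), with Ndufa1 at -0.14 (SE 0.12), which was -0.054 without control 4 and 0.14 with normexp as planned. Mitochondrial biogenesis genes were higher for 9 and lower for 6 of 15 (adjusted p = 0.712), with Mfn2 at 0.17 (SE 0.11) and a further probe of it at -0.040, and glucose genes were higher for 13 and lower for 11 of 24 (adjusted p = 0.691), with Pdk4 at -0.37 (SE 0.33). Mfn2 differed by 0.43 with normexp as planned and 0.045 with its kept probes averaged. Pdk4 differed by -0.58 without control 1 or dtg 1, -0.24 without control 3, -0.20 without control 4, -0.17 without dtg 2, 0.30 within slide 1 and 0.017 with array weights. Antioxidant genes were higher for 16 and lower for 9 of 25 (adjusted p = 0.543), with Gpx3 at -0.43 (SE 0.21) and Gpx1 at 0.16 (SE 0.10). Gpx3 differed by -0.62 without control 2, -0.027 within slide 1 and -0.84 within slide 2, and Gpx1 by 0.080 with median scaling and 0.40 with normexp as planned. The oxidative phosphorylation list was called as lower without control 1 (adjusted p = 0.032). With normexp as planned, oxidative phosphorylation (adjusted p = 1.8e-07), mitochondrial biogenesis (adjusted p = 0.00721), glucose (adjusted p = 2.02e-05) and antioxidant genes (adjusted p = 4.59e-06) were called as higher, and with dark spots left out of normexp none of the 4 was. Over the alternatives these adjusted p ranged up to 0.978, 0.991, 0.991 and 0.994.

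Matrix genes and markers of other cell types did not pass with all 8 hearts and the chosen processing, but 6 of these 8 lists did under at least 1 alternative. Extracellular matrix genes were higher for 13 and lower for 20 of 33 (camera adjusted p = 0.151), with Mmp9 at -0.35 (SE 0.20) and Thbs1 at 0.15 (SE 0.11). Mmp9 differed by -0.66 with quantile normalization and -0.028 with array weights, and Thbs1 by 0.089 without dtg 2 and 0.061 with normexp as planned. The matrix list was called as lower without dtg 2 (adjusted p = 0.0236) and without a filter on dim probes (adjusted p = 0.0419), with a range up to 0.96 over the alternatives. Fibroblast markers were higher for 4 and lower for 10 of 14 (adjusted p = 0.177), endothelial markers for 4 and 12 of 16 (adjusted p = 0.132) and adipocyte markers for 2 and 11 of 13 (adjusted p = 0.0851). With slide as a block the adipocyte list was called as lower (adjusted p = 0.0364, median -0.12), as it was within slide 2 (adjusted p = 0.00568), without control 1 (adjusted p = 1.6e-05), without dtg 3 (adjusted p = 0.00318), without a filter on dim probes (adjusted p = 0.01) and with normexp without dark spots (adjusted p = 0.0338). Within slide 1 its median was 0.094 (adjusted p = 0.947, the highest of the alternatives). Fibroblast markers were called as lower without control 1 (adjusted p = 0.0311), without control 2 (adjusted p = 0.035) and within slide 2 (adjusted p = 0.036), and as higher with normexp as planned (adjusted p = 0.0273), with a range up to 0.96. Endothelial markers were called as lower without control 2 (adjusted p = 0.035), without dtg 2 (adjusted p = 0.0438) and without a filter on dim probes (adjusted p = 0.0419), with a range up to 0.956. Macrophage and leukocyte markers were divided evenly, 11 higher and 11 lower of 22 (adjusted p = 0.996). Neuronal and Schwann cell markers were higher for 3 and lower for 8 of 11 (adjusted p = 0.151), skeletal muscle markers for 3 and 6 of 9 (adjusted p = 0.151) and lung and thymus markers for 2 and 2 of 4 (adjusted p = 0.86). Neuronal markers were called as lower with probes above background on all 8 arrays (adjusted p = 0.0262) and with normexp as planned (adjusted p = 0.00702), with a range up to 0.908. Skeletal muscle markers were called as lower without control 3 (adjusted p = 0.0437), without dtg 3 (adjusted p = 0.027), with array weights (adjusted p = 0.0222) and with either covariate chosen after seeing the data, the first principal component (adjusted p = 0.0458) or 3 atrial genes (adjusted p = 0.0362), with a range up to 0.908.

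Among stress, immune and growth lists, paracrine growth factor genes were higher for 12 and lower for 8 of 20 (camera adjusted p = 0.709). That list held neuregulin (Nrg1) at 0.46 (SE 0.16), not past the adjusted threshold, and at 0.29 within slide 1 and 0.11 with normexp as planned. Cytokine genes were higher for 13 and lower for 5 of 18 (adjusted p = 0.463), interferon genes for 10 and 10 of 20 (adjusted p = 0.796) and immediate early genes for 9 and 11 of 20 (adjusted p = 0.205). Heat shock and unfolded protein genes were higher for 12 and lower for 10 of 22 (adjusted p = 0.86), p53 and apoptosis genes for 10 and 10 of 20 (adjusted p = 0.996), cell cycle genes for 14 and 4 of 18 (adjusted p = 0.179) and ribosomal protein genes for 22 and 6 of 28 (adjusted p = 0.543). Ribosomal protein genes were called as higher within slide 1 (adjusted p = 0.000337), without control 4 (adjusted p = 8.66e-06), with array weights (adjusted p = 0.00796), with the atrial covariate (adjusted p = 0.0362) and with normexp as planned (adjusted p = 5.14e-11), and as lower within slide 2 (adjusted p = 0.0461), with a range up to 0.978. Cell cycle genes were called as higher without control 1 (adjusted p = 0.000363, with a range up to 0.975), heat shock genes with normexp as planned (adjusted p = 0.00331, up to 0.978) and interferon genes without control 4, dtg 3 and dtg 4 and with slide as a block (adjusted p = 0.0175, up to 0.991). The median, the mean and the direction of camera's test were not all of one sign for the sarcomere, calcium handling, glucose, interferon, heat shock and macrophage lists.

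**Figure D4:**
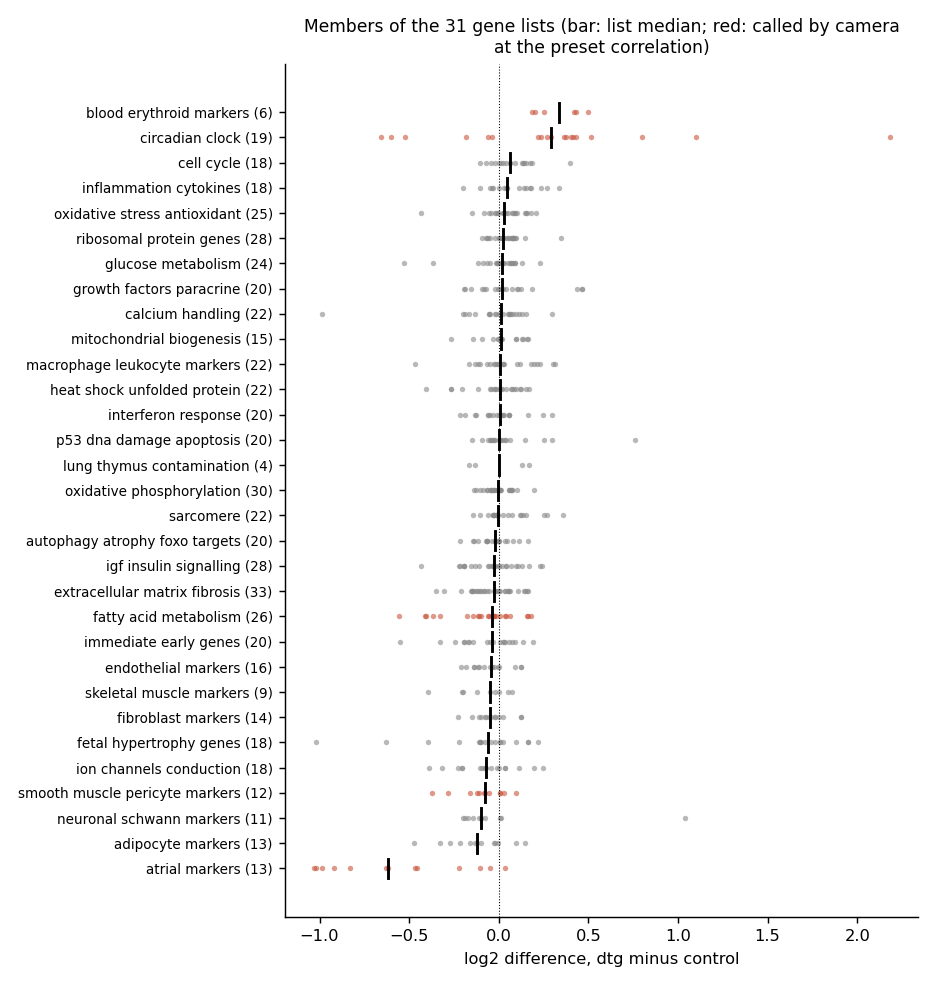
Log2 difference, dtg minus control (x axis), of every measured member of the 31 gene lists (rows, with the number of measured members), where each point is a gene, the black bar the list median and red marks the 5 lists that camera called at its preset correlation. Medians range from -0.62 for atrial markers to 0.34 for erythroid markers.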

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

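The outlier test of this part was not chosen after its result was seen. Among the genes it covered, the number taken per list was set after the calls were seen, and Sln was chosen after its values were seen. Single samples were set against the other 3 of their group for the named genes, for the share of probes above background, for array brightness and for the mean of 3 atrial genes. In 13 of 168 groups the highest or lowest sample lay far from the rest, where chance gives about 8. In control 1, log2 signal was above that of the other controls for Cldn5 (2.71), Tie1 (1.42), Calr (3.43) and Mcm5 (-1.59). Gpx3 was low in control 2 (3.05), Gab3 was low in control 3 (4.55), and Ndufa1 (7.18) and Dpt (1.52) were high in control 4. Among dtg hearts, Esrrg was high (0.87) and Acot1 low (1.20) in dtg 2, Nppb was high (6.20) and Alas2 low (1.58) in dtg 3, and Tnni2 was high (-0.17) in dtg 4. Leaving out dtg 3 took the erythroid list from a median of 0.34 to 0.45, with its call kept at the preset correlation. With all 8 hearts and an estimated correlation that call was lost (adjusted p = 0.39).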

How the results depend on the processing

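The covariates, the normexp correction without dark spots and the fit without control 4, dtg 3 and dtg 4 were tests chosen after seeing the data. The gene count from limma was 0 in every alternative tried, with 13 to 779 at an unadjusted p under 0.05, and Igf1r stayed lower in dtg hearts in all of them, between -0.73 and -0.14, without passing. The number of lists called was 5 and moved to 13 with normexp as planned, 8 without a filter, 2 without control 4, dtg 3 and dtg 4 (slide as a block), 0 with an estimated correlation and 0 with fry, and it ranged from 2 to 8 when single samples were left out. Without control 1 it was 8, without control 3 or control 4 it was 3, and without dtg 4 it was 2. Of the 26 lists not called, 18 were called in at least 1 of the 27 alternatives, adipocyte and ribosomal protein genes in 6 each. Sarcomere, mitochondrial biogenesis, glucose, heat shock and antioxidant genes were called only with normexp as planned. With dark spots left out of normexp, adipocyte genes alone of the 26 lists were called. A turn of camera's direction is listed next only where the list was called with the chosen processing or in that alternative. In 113 further pairs of list and alternative the direction, of camera or fry, turned with no call in either. Camera's direction turned under normexp for oxidative phosphorylation (median 0.26), fatty acid (0.23), glucose (0.28), fibroblast (0.17), smooth muscle (0.11), heat shock (0.23) and autophagy genes (0.18). The fit itself shows the cause on control 4 and dtg 4, where a few spots darker than their background pulled it, and with those spots left out 6 lists were called and the medians of fatty acid and smooth muscle genes were -0.026 and -0.096; of these 7 lists, glucose genes alone stayed turned, without a call. Camera's direction also turned within slide 1 for fatty acid (0.026) and atrial genes (1.36), within slide 2 for erythroid (its median still positive, 0.039), clock (-0.0050) and ribosomal protein genes (-0.082), under array weights for atrial genes (0.47), and for interferon genes (0.13) without control 4, dtg 3 and dtg 4. Within slide 2 the smooth muscle median was 0.032, although camera's direction did not turn. For these the cause was not tested. Of 27 alternatives, the erythroid list kept its call in 24, atrial in 18, fatty acid in 17, smooth muscle in 14 and clock in 14. The intensity trend entered the gene test alone, so in that alternative the list calls repeat the main ones. Quantile normalization and the deposited values are nearly the same processing, so the alternatives are not independent. The atrial covariate was made of members of the atrial list, so the atrial loss under it carries no weight. The first principal component and the mean of Myl7, Myl4 and Sln as covariates left 0 genes and 4 and 6 lists. No further probe of Igf1r was matched, so that alternative gave no value.

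Whether the replicate numbers pair the samples cannot be told from these values. Same-numbered samples deviated from their group means with correlations of 0.542, -0.545, 0.152 and 0.161 for numbers 1 to 4. Controls 1 to 4 correlated best with dtg 1, dtg 1, dtg 2 and dtg 4. Samples numbered 1 and 3 shared a slide and those numbered 2 and 4 did not, so slide enters these correlations. With the replicate block, 0 genes and 5 lists passed, 276 genes reached an unadjusted p under 0.05, and Igf1r differed by -0.43 (SE 0.108).

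Signal over background limits dim genes: with probes above background on all 8 arrays, 18376 were tested, 0 passed and 136 reached an unadjusted p under 0.05.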

Other observations

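The counts of genes over splits, the slide split, the splits balanced over slides and the correlations of Arntl with Dbp, over all hearts and within slides, were tests chosen only after the result was seen.

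Fewer genes than chance gives reached an unadjusted p under 0.05 between the groups, 160 against 1072. Of the 35 splits of the 8 hearts into 4 and 4, 2 gave as few, the fewest elsewhere being 115, so chance is not excluded, while the 0 genes past the adjusted threshold cannot be weighed this way, because every split gives at least 0. Among the 18 splits that, like the real one, put 2 samples of each slide on each side, the real 160 was the lowest and the next was 171, but 18 splits are too few for a share under 0.05. The split by slide gave 2595 genes past the adjusted threshold, where the next highest gave 5, which points to a structure of the samples and is consistent with slide being part of the cause. Slide as the whole cause is argued against, because with slide as a block the count was 252, and so is noise of dim probes, because the share was 0.74% among probes above background on all 8 arrays. The count rose to 779 with array weights, and to 665 without control 4, dtg 3 and dtg 4 with slide as a block. Why it rose there was not tested.

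The list calls can be set against the same splits. At the preset correlation 16 of the 35 splits gave as many lists as the real 5, and the highest of the others was 9, so chance is not excluded. A p as small as the real one came from 3 splits for the erythroid list (smallest elsewhere 4.12e-14), 6 for the atrial list (1.50e-16), 5 for the fatty acid list (1.10e-11) and 5 for the clock list (0.000157), so chance is not excluded for these. For the smooth muscle list only the real split, 1 of 35, gave so small a p (smallest elsewhere 0.00155). No allowance was made for the 31 lists tested, from which these 5 were taken because camera called them in the real split. That choice favours a small p in the real split, so this share alone cannot exclude chance for the smooth muscle list. Among the 18 splits balanced over slides, 7 gave as many lists (highest of the others 9), and a p as small came from 3 for the erythroid, fatty acid and clock lists each, 5 for the atrial list and 1 for the smooth muscle list (smallest elsewhere 0.0031), again too few splits for a share under 0.05.

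Clock genes may differ with the time of day at which each heart was taken. Arntl and Dbp, which peak at opposite times of day, ran in opposite order over all 8 hearts (Pearson's r = -0.96, exact permutation p = 2.48e-05; Spearman's rho = -1, exact permutation p = 4.96e-05, each the smallest its permutations can give). Without control 1 and control 2, the samples farthest from the median of Dbp, r was -0.971 (1 relation was computed), and within slides 1 and 2, with 4 samples each, it was -0.972 and -0.937 (exact permutation p = 0.0417 for each, the smallest 4 samples can give). Leaving out single hearts took the adjusted p of the list (camera) to as much as 0.359. The prediction written before the test took such a lost call as the outcome against genotype shown by every heart, so that prediction failed. The list median stayed positive in all 8 fits, between 0.19 and 0.43, but its sign was not part of the prediction. A difference by genotype in some of the hearts stays open. A shift of the clock by genotype would also move Arntl and Dbp oppositely, so their relation cannot tell time of day from genotype. The hours of collection are not given in the sources used here, so time of day stays a hypothesis.

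Erythroid genes higher in dtg hearts may reflect blood left in the tissue or the genotype. At the preset correlation the list kept its call whichever heart was left out, with an adjusted p of at most 0.0236, but the call was lost over all 8 hearts with an estimated correlation (adjusted p = 0.39) and within slide 2, and other splits matched it. Of 18 further red cell genes written down before the test, 13 were measured and 7 were higher, and their median difference of 0.0039 lay at the 48.87th percentile of 10000 random lists matched on expression. The prediction written before the test took a median below the middle of the random lists as the outcome against blood, and resampling was not part of it. Resampling the genes moved that place between 3.79 and 99.6, so blood cannot be told apart from genotype by these genes. The brightest of them, Fech and Ank1, which are also expressed outside red cells, had mean log2 signals of 4.47 and 3.94 and differences of 0.0039 and -0.062.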
